A study of Homo sapiens with 12 samples.

How the data were processed

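RNA-seq was run on CFPAC-1 and BxPC-3, 2 human pancreatic ductal adenocarcinoma lines, each under normal culture (control) and after 48 h of serum starvation to induce primary cilia (induced). There were 3 libraries in each of the 4 groups and 12 libraries in all. Total RNA was extracted with TRIzol and made into libraries by a standard Illumina protocol, per the labels' protocols. The submitters' processing notes name FastQC, StringTie and the human genome build GRCh38, without versions. The aligner, the gene annotation and the use of strand are not given in the sources used here.

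The deposited table gives 1 value per gene and library for 60564 genes, of which 2796 carry no symbol. The authors deposited the values as log2 of FPKM plus 1, per the file headers and the values, which run from 0 to 13.8. FPKM, fragments per kilobase of transcript and per 1000000 mapped fragments, is relative to each library's own total, so a few abundant transcripts shift the values of the rest. Mitochondrially encoded genes took 11.6% to 34.0% of the summed FPKM of a library. FPKM was recovered by undoing the log2 offset, and summed to between 258299 and 315377 per library. Every column was matched to a sample by its name. Of the gene identifiers, 58457 (96.5%) were found in GENCODE release 29, an annotation of the same named build, which supplied the coordinates, 1-based on GRCh38.

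The table holds no read counts, so the depth of each library is unknown in absolute terms. Low values of genes near 1 read gave an estimate of relative depth of 0.633 to 1 of the deepest library, from a weak peak that stood 2.07 to 2.93 times over its surroundings, and whole reads were not recovered. No counting interval can be given for a low value, and a gene listed at 0 may lie under the limit of detection. Without the use of strand, reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as AKR1C1 and AKR1C2, the HLA genes, the histone genes and the ribosomal protein genes with their pseudogenes may share reads, so their single values are uncertain.

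Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, 12860 genes, 11125 of them protein coding, and 23450 genes were listed at 0 in every library. The model was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the 4 group means fitted over all 12 libraries (8 residual degrees of freedom), without a trend, a robust setting or a replicate block. All tests were two-sided with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Every log2 change is a difference of mean log2(FPKM + 1), induced minus control, which understates the change of genes of low level. The contrasts were induced against control in each line and the difference of these changes, BxPC-3 minus CFPAC-1. The overlap of calls in the lines was tested with a one-sided Fisher's exact test per direction; the lines have no library in common.

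Before the data were examined, 43 gene lists were fixed. They cover intraflagellar transport, the BBSome, the transition zone, ciliary membrane and trafficking, centriole and basal body, cilium disassembly, the motile cilia programme, Hedgehog, immediate-early and SRF, YAP TEAD, TGF-beta, Wnt and Notch targets. They further cover G1/S and DNA replication, G2/M and mitosis, quiescence and FOXO targets, p53 targets, cholesterol synthesis and SREBP2 targets, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, and also ATF4 and amino acid response, unfolded protein response, autophagy and lysosome, NRF2 targets, interferon response, antigen presentation, NF-kB and inflammatory cytokines, classical and basal-like pancreatic cancer, duct cell and mucin markers, epithelial junction, mesenchymal transition and extracellular matrix. Lists of other cell types (fibroblast, immune cell, endothelial, acinar and endocrine markers) and of RNA quality (mitochondrially encoded mRNAs, replication-dependent histones, small nuclear, nucleolar and 7SL RNAs) complete the 43. The 39 lists with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 78 tests of the lines and separately over the tests of the difference. Camera with a correlation estimated per list was an alternative. A list's direction is the sign of its median log2 change. Camera compares a list with the other tested genes, not with 0. The median log2 change of all tested genes was -0.092 in CFPAC-1, 0.063 in BxPC-3 and 0.162 for the difference between the lines.

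The genes named were also fixed by rule beforehand. In each line they are up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold, with no overlap of induced and control values, a mean FPKM of at least 5 in the higher group and a symbol that is not a clone, LINC or small RNA name. For each described list they are up to 2 members with the largest rise and 2 with the largest fall past the threshold, or, where none passed, the 2 of highest level; the latter are given for the lists that passed in BxPC-3 and for a few others. For the difference between lines they are the 5 largest per direction under the same filters, with no overlap required in either of the lines, and for both lines the shared genes. IFT88, GLI1, PTCH1, SMO, FOXJ1, MKI67, CCNB1, MCM2, CDKN1B, AURKA, HDAC6, FOS, MYC, VIM, CDH1, TXNIP, GAPDH and ACTB were to be given in any case. Some further genes that these rules select are not reported here. Genes used to describe the libraries that stand apart were chosen after their values were seen.

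The procedure was tested on simulated data for 12860 genes, 200 of them changed. With a log2 change of 1, it called 26% of the changed genes in CFPAC-1 and 27% in BxPC-3; with a log2 change of 2, it called 91% and 94%. False calls numbered 1 in CFPAC-1 (0.848% of calls) and 4 in BxPC-3 (3.2%). A list shifted in the BxPC-3 simulation was called, and of the 77 other list tests 0 were. The simulated noise was independent between genes and between libraries, without the split of libraries within groups that the data show. It therefore cannot tell how many false genes or lists arise where genes vary together.

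The alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, scaling to a sum of 1000000 per library (TPM), median-of-ratios scaling, quantile normalization, each line fitted alone, a mean-variance trend, a replicate block and leaving out each library in turn. Added after seeing the data were fits without the libraries labelled CFPAC-1 control 2 and 3, with a term for library number 1, with libraries numbered 2 and 3 only, and combinations of these. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.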

Results

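Gene expression was measured in CFPAC-1 and BxPC-3, established human pancreatic ductal adenocarcinoma lines, to learn what changes when the cells are made to grow primary cilia, the single sensory organelle that many resting cells carry. Cells were kept in normal culture (control) or starved of serum for 48 h (induced). The series text gives ciliated cells as 7% of control and 39% of induced CFPAC-1 cells, and as 5% and 78% of BxPC-3 cells, without an error. Each of the 4 groups has 3 libraries, and 12860 genes were tested. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between libraries, which may be technical. The depth in reads is not known; the relative depth was estimated at 0.633 to 1 of the deepest library. Serum starvation and cilium growth came together in every induced library, so the comparisons are of starved, ciliated cultures with fed ones.

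The libraries did not all group by their labels. The libraries labelled CFPAC-1 control 2 and 3 correlated at r = 0.990 with each other across tested genes, which are not independent replicates. Their mean r was 0.803 with the other 4 libraries of that line, against 0.944 among those 4, and 0.785 with BxPC-3. The library labelled CFPAC-1 control 1 had a mean r of 0.932 with the induced CFPAC-1 libraries and of 0.814 with control 2 and 3. Expression of 40 genes was at least 10 FPKM in each of those 4 libraries and at most 0.2 FPKM in control 2 and 3, and 39 genes showed the reverse. Thus CDKN2A, a cell cycle inhibitor, stood at 49.1 FPKM in control 1, at 25.2, 58.2 and 52.1 FPKM in the induced libraries, and was listed at 0 in control 2 and 3. LDHB, a lactate dehydrogenase subunit, was listed at 0 in control 1 and in the 3 induced libraries and stood at 177 and 186 FPKM in control 2 and 3. The first principal component (52.0% of variance) parted the lines and the second (25.6%) these libraries. For this reason CFPAC-1 counts, gene lists and the genes of largest change are given with all libraries and, beside them, with control 2 and 3 left out. In the latter fit the lone control is assumed to vary like the other groups. P-values of that fit measure no spread between CFPAC-1 control libraries, and those of lists reflect agreement among genes within 1 control library.

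Within each group, libraries 2 and 3 also lay closer to each other (SD of their log2 differences 0.259 to 0.282) than to library 1. The SD of the log2 difference between library 1 and the mean of 2 and 3 was 1.08 in CFPAC-1 control, 0.593 in CFPAC-1 induced, 0.534 in BxPC-3 control and 0.539 in BxPC-3 induced. Libraries 2 and 3 held different values and were counted separately, but different values do not show that they came from separate cultures. If they are repeats of 1 culture, each group holds fewer than 3 independent samples. In BxPC-3, control 1 also correlated better with the induced libraries (mean r = 0.963) than with control 2 and 3 (0.950). Median changes within library number 1 and within numbers 2 and 3 are therefore given for the lists that passed in BxPC-3.

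**Figure D1:**
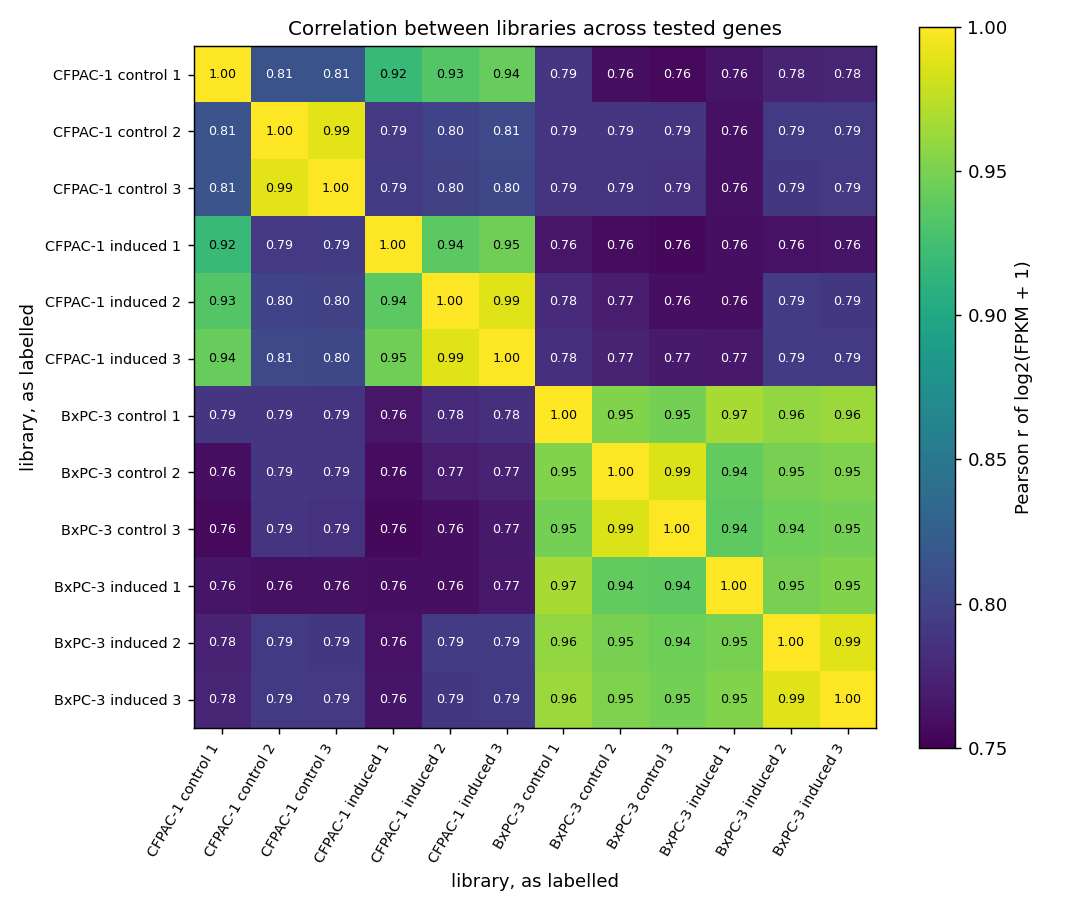
Pearson correlation of log2(FPKM + 1) between each pair of the 12 libraries across the tested genes (colour scale from 0.75 to 1, values in the cells). The libraries labelled CFPAC-1 control 2 and 3 correlated at 0.99 with each other and at 0.79 to 0.81 with the remaining libraries of that line.

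In BxPC-3, the largest increase on induction among the genes that passed the test was in S100A7 (psoriasin, an antimicrobial calcium-binding protein; ENSG00000143556, chromosome 1, 153457744 to 153460701). It rose from 0.338 ± 0.296 to 80.4 ± 61.2 FPKM (SD, n = 3 per group), a log2 change of 5.34 with a standard error of 0.69. That error uses the spread shared by all 12 libraries, which is lowered where a gene is silent in CFPAC-1. S100A7, like S100A8, was listed at 0 in every CFPAC-1 library. With BxPC-3 fitted alone the adjusted p of S100A7 was 0.164 (limma, Benjamini-Hochberg). Its neighbour S100A8 (a subunit of calprotectin; chromosome 1, 153390032 to 153391188) rose from 1.74 ± 1.13 to 68.5 ± 45.7 FPKM, a log2 change of 4.37. DUOXA2 and DUOX2, which lie side by side on chromosome 15 (45114321 to 45118421 and 45092650 to 45114344), rose by 3.03 and 2.10. DUOX2 encodes a hydrogen peroxide-producing oxidase and DUOXA2 its maturation factor. The complement factor gene CFB rose by 2.33, the chemokine gene PPBP by 2.29, the salivary cystatin gene CST4 by 2.23 and the neuronal enolase gene ENO2 by 1.91. IGFBP5, which binds insulin-like growth factors (ENSG00000115461, chromosome 2, 216672105 to 216695525), fell by 3.45, from 35.8 ± 23.3 to 1.76 ± 0.881 FPKM. The cationic amino acid transporter gene SLC7A2 fell by 2.14 and the epiplakin gene EPPK1 by 1.34.

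Of 12860 genes, 43 passed the threshold in BxPC-3 (38 up, 5 down; limma, Benjamini-Hochberg adjusted p under 0.05), and 38 of these changed at least 2-fold, against 1096 genes at an unadjusted p under 0.05. The adjusted p was 0.00801 for S100A7, S100A8 and DUOXA2, 0.00876 for PPBP, 0.0171 for IGFBP5, 0.0206 for CST4, 0.0358 for DUOX2 and 0.0417 for CFB, ENO2, SLC7A2 and EPPK1. Induced and control values did not overlap for any of the 43 genes, nor for 17.2% of all tested genes, where chance gives 10%. The log2 changes of S100A7 were 2.85 within library number 1 and 6.58 within numbers 2 and 3, and across all tested genes such changes correlated at -0.0091. With the replicate number as a block, 0 genes passed by limma, with an adjusted p of 0.106 for S100A7, of 0.167 for S100A8 and of 0.065 for DUOXA2. The count rested on single libraries: it was 4, 2, 4 and 7 without BxPC-3 control 2, control 3, induced 2 or induced 3, and 249 and 78 without BxPC-3 control 1 or induced 1. It was 90, 24 and 26 without CFPAC-1 control 1, 2 or 3, and 26 and 24 without CFPAC-1 induced 2 or 3. Each of the 11 genes named lost its call without any 1 of BxPC-3 control 2, control 3, induced 2 and induced 3 (for S100A7 adjusted p = 0.0529, 0.065, 0.0532 and 0.0647). Without CFPAC-1 control 2 and 3, 52 genes passed in BxPC-3, 35 of them among the 43, and DUOX2, SLC7A2 and EPPK1 did not (0.0558, 0.0606 and 0.056).

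Genes of glycolysis and of the response to low oxygen were higher in induced BxPC-3 cells as a group. Of the 30 tested members 2 rose, 0 fell and 28 did not pass, 13 rose when adjusted over the list alone, and 26 had a positive change. The list's median log2 change was 0.59 (camera, Benjamini-Hochberg adjusted p = 2e-11; adjusted p = 0.327 with an estimated correlation), with 0.70 within library number 1 and 0.69 within numbers 2 and 3. PGK1, the glycolytic phosphoglycerate kinase (ENSG00000102144, chromosome X, 77910739 to 78129296), rose from 166 ± 26.0 to 352 ± 4.65 FPKM, and ENO2 from 1.18 ± 0.254 to 7.54 ± 3.32 FPKM. The hypoxia-induced carbonic anhydrase gene CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159) went from 1.03 ± 0.224 to 70.7 ± 11.5 FPKM, a log2 change of 5.13 with an adjusted p of 0.223. CA9 varied widely among the CFPAC-1 control libraries, which share the estimate of spread; without CFPAC-1 control 2 and 3 its adjusted p in BxPC-3 was 5.33e-06. The reference gene GAPDH, also of this list, stood at 2726 ± 425 and 4044 ± 586 FPKM (log2 change 0.57, adjusted p = 0.506).

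In the other lists that passed in BxPC-3, no single member passed the test over all genes. The lists' medians are therefore described (camera, Benjamini-Hochberg adjusted p), with the log2 changes of the 2 members of highest mean level over the 4 groups of both lines. Another split of the BxPC-3 libraries gave 16 lists, against 15 for the real one, so the number of lists does not set the real groups apart. The median of the 39 G1/S and DNA replication genes was 0.42 (adjusted p = 6.42e-06; adjusted p = 0.533 with an estimated correlation), and that of the 47 G2/M and mitosis genes 0.26 (0.0154; 0.717), with 0 members up or down when adjusted over the list alone. These 2 medians were -0.08 and -0.06 within library number 1 and 0.60 and 0.50 within numbers 2 and 3. PCNA, the replication clamp, had a log2 change of 0.60 and the helicase gene MCM7 one of 0.03, CDC20 and UBE2C, which act with the complex that ends mitosis, had 0.11 and 0.28, and MKI67, a marker of cycling cells, stood at 11.9 ± 3.52 and 11.7 ± 5.01 FPKM. The changes of MCM2, CCNB1, AURKA and TXNIP were 0.42, 0.21, 0.31 and 2.13, none past the threshold. Of these 9 genes all but PCNA and TXNIP had opposite signs within number 1 and within numbers 2 and 3. Without BxPC-3 control 2, control 3 or induced 1 the adjusted p of the G2/M list was 0.178, 0.185 and 0.107.

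Antigen presentation (13 genes) had a median of 0.29 (camera, Benjamini-Hochberg adjusted p = 0.00415; adjusted p = 0.357 with an estimated correlation; 4 up when adjusted over the list alone). Interferon response (27 genes) had a median of 0.32 (0.0173; adjusted p = 0.501 with an estimated correlation; 1 up over the list alone), and autophagy and lysosome (37 genes) one of 0.35 (0.0112; 0.519; 1 up). These 3 medians were 0.16, 0.04 and 0.14 within library number 1 and 0.46, 0.50 and 0.38 within numbers 2 and 3. Changes were 0.38 for B2M, 0.32 for BST2, -0.12 for ISG15, 0.35 for PSAP and -0.58 for SQSTM1, with opposite signs within number 1 and within numbers 2 and 3 for BST2, ISG15 and PSAP. PSAP was high only in CFPAC-1. In BxPC-3 it stood at 0, 0.267 and 0.287 FPKM in control and at 2.13, 0.0171 and 0.0615 FPKM in induced libraries, so its change rests on 1 library near the floor. The interferon list passed no longer without BxPC-3 control 2, control 3 or induced 1 (adjusted p = 0.132, 0.168 and 0.137) or at a mean FPKM of at least 5 (0.27), nor the autophagy list without control 3 or induced 1 (0.0897 and 0.0882).

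Of the lists of RNA quality, 2 were higher in induced BxPC-3 cells, both with a negative median within library number 1. Replication-dependent histones (11 genes) had a median of 0.60 (camera, Benjamini-Hochberg adjusted p = 0.000354; adjusted p = 0.501 with an estimated correlation; 5 up when adjusted over the list alone), with -0.12 within number 1 and 0.96 within numbers 2 and 3. Small nuclear, nucleolar and 7SL RNAs (10 genes), a sign of how RNA was selected, had a median of 0.63 (0.0153; adjusted p = 0.501 with an estimated correlation; 0 over the list alone), with -0.21 within number 1 and 1.11 within numbers 2 and 3, and 0.10 without BxPC-3 control 3. Changes were 1.06 for HIST1H1C, 0.60 for HIST1H2BK, 0.80 for RN7SL1 and 0.76 for RN7SL2, each negative within number 1 and none past the threshold. The small nuclear list did not pass without BxPC-3 control 3, induced 2 or CFPAC-1 control 1 (adjusted p = 0.932, 0.0607 and 0.0514), nor at a mean FPKM of at least 5 (0.0991) or with BxPC-3 fitted alone (0.0784).

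Lower as groups in induced BxPC-3 cells were cholesterol synthesis (25 genes, median -0.38, camera with Benjamini-Hochberg adjusted p = 4.1e-06, 1 down when adjusted over the list alone), ATF4 and amino acid response (28 genes, -0.31, 0.000128, 0 down), and mitochondrially encoded mRNAs, a list of RNA quality (13 genes, -0.43, 0.000218, 0 down). So were immediate-early and SRF targets (29 genes, -0.36, 0.000493, 0 down), fatty acid synthesis (20 genes, -0.22, 0.00181, 1 down), NRF2 targets (21 genes, -0.16, 0.00904, 2 down) and Wnt targets (12 genes, -0.39, 0.0328, 0 down and 1 up). With an estimated correlation the adjusted p of these 7 lists was 0.501, 0.425, 0.501, 0.501, 0.466, 0.501 and 0.357. Medians within library number 1 and within numbers 2 and 3 were -0.04 and -0.58 for cholesterol synthesis, -0.15 and -0.36 for ATF4 and -0.53 and -0.32 for mitochondrial mRNAs. They were 0.38 and -0.42 for immediate-early genes, 0.02 and -0.47 for Wnt targets, -0.05 and -0.31 for fatty acid synthesis and -0.05 and -0.18 for NRF2 targets. Changes of members of high level were -0.17 for CYP51A1, -0.69 for ATF4, -0.34 for SLC7A5, -0.57 for MT-CO1, -0.43 for MT-CO3, -0.42 for ACTB and -0.42 for ACTG1. They were -1.20 for SCD, -0.82 for FASN, 0.54 for FTH1, -0.09 for FTL, 0.10 for CCND1 and -0.92 for DKK1, with opposite signs within number 1 and within numbers 2 and 3 for CYP51A1, SCD, FTH1 and FTL. The mitochondrial list did not pass after quantile normalization (adjusted p = 0.191). The Wnt list lost its call without BxPC-3 control 1, control 3 or induced 2 (adjusted p = 0.0502, 0.0776 and 0.0873) and the NRF2 list without induced 1 (0.307). At a mean FPKM of at least 5 the Wnt and NRF2 lists did not pass (0.102 and 0.0629), and without a filter the Wnt list had a median of -0.052 (0.107).

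The genes that build and run the cilium did not pass as groups in BxPC-3, although its share of ciliated cells was the higher. Median log2 changes were 0.05 for 28 intraflagellar transport genes, 0.13 for 10 BBSome genes, 0.14 for 18 transition zone genes and 0.00 for 19 ciliary membrane and trafficking genes. They were 0.05 for 22 centriole and basal body genes, 0.15 for 13 cilium disassembly genes, -0.25 for 5 motile cilia genes and -0.01 for 11 Hedgehog pathway genes. Their camera p-values with Benjamini-Hochberg adjustment ran from 0.305 to 0.883, 0 members passed over all genes and 0 when adjusted over the list alone. GLI1, a target of Hedgehog signalling, stood at 0, 0.0364 and 0.0105 FPKM in BxPC-3 control and at 0.0133, 0 and 0.0111 FPKM in induced libraries. At that level its log2 change of -0.01 cannot show whether the target changed. The deacetylase gene HDAC6 had a log2 change of -0.13.

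In CFPAC-1 with all libraries, the genes of largest increase that passed the test included IGFBP1 and IGFBP3, neighbouring genes for binding proteins of insulin-like growth factors (chromosome 7, 45888357 to 45893668 and 45912245 to 45921874). IGFBP1 rose by 7.03 log2 units, from 22.7 ± 38.9 to 690 ± 322 FPKM (SD, n = 3), and IGFBP3 by 5.20, from 11.9 ± 16.4 to 262 ± 16.8 FPKM. The aldo-keto reductase genes AKR1C2 and AKR1C1 rose by 5.87 and 5.52, CA9 by 5.80 (from 28.1 ± 48.6 to 248 ± 53.3 FPKM), the laminin gene LAMB3 by 5.56, TXNIP, an inhibitor of glucose uptake, by 5.43 and the hypoxia- and stress-induced gene NDRG1 (chromosome 8, 133237171 to 133302022) by 5.28. With CFPAC-1 control 2 and 3 left out, the log2 changes were 3.19 for IGFBP1, 3.05 for IGFBP3, 2.02 for AKR1C2, 1.59 for AKR1C1, 1.52 for CA9 and 2.96 for NDRG1, all past the threshold. They were 1.70 for LAMB3 and 1.99 for TXNIP, which were not (limma, Benjamini-Hochberg adjusted p = 0.0724 and 0.237). The largest falls, in AHNAK (-3.16), F2RL1 (-3.07), TIMM50 (-3.02), PSMC4 (-2.99), MXRA8 (-2.99), ACAT2 (-2.98), ADORA2B (-2.92) and TUBA1A (-2.83), had log2 changes of -0.40 to -0.76 without those libraries and adjusted p-values of 0.391 to 0.798. CA9 lost its call without CFPAC-1 control 2, control 3, induced 2 or induced 3 (adjusted p = 0.0693, 0.0698, 0.0538 and 0.0515).

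With all libraries, 2138 genes passed in CFPAC-1 (1010 up, 1128 down; limma, Benjamini-Hochberg adjusted p under 0.05), 1143 of them at least 2-fold, and 4633 at an unadjusted p under 0.05. With control 2 and 3 left out, 222 genes passed (136 up, 86 down), 212 at least 2-fold, and 2324 at an unadjusted p under 0.05. Of the 2138 genes, 140 were called in both fits and 12 had the opposite sign in the second. The limma adjusted p with all libraries was 0.00585 for IGFBP1, 0.00299 for IGFBP3, 0.00941 for AKR1C2, 0.0133 for AKR1C1, 0.0153 for CA9 and 0.00259 for NDRG1. Without control 2 and 3 it was, in the same order, 0.0453, 0.0483, 0.00338, 0.00861, 0.0382 and 0.0173. Median-of-ratios scaling changed the split of calls to 1285 up and 669 down. The count was 5403 without control 1, 506 without control 2 or control 3, and 776 and 803 without induced 2 or 3. Induced and control values did not overlap for 1958 of the 2138 genes and for 31.6% of all tested genes, where chance gives 10%. Leaving out control libraries cannot turn the sign of such genes, so the low number of opposite signs was largely fixed in advance.

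The glycolysis and hypoxia list rose in CFPAC-1 as in BxPC-3. Of 30 genes, 18 rose, 0 fell and 12 did not pass, with 21 up and 1 down when adjusted over the list alone. The median log2 change was 1.23 (camera, Benjamini-Hochberg adjusted p = 5.77e-12; adjusted p = 0.327 with an estimated correlation), and 1.02 with control 2 and 3 left out (adjusted p = 4.57e-10). NDRG1 and CA9 led it, and GAPDH rose from 1866 ± 466 to 4246 ± 766 FPKM (adjusted p = 0.00783; 0.161 without control 2 and 3).

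Genes of cell division fell in CFPAC-1. Of 47 G2/M and mitosis genes, 24 fell, 0 rose and 23 did not pass (32 down when adjusted over the list alone), with a median of -0.98 (camera, Benjamini-Hochberg adjusted p = 1.63e-11; adjusted p = 0.466 with an estimated correlation) and of -0.91 with control 2 and 3 left out. MKI67 went from 12.2 ± 1.61 to 3.18 ± 0.476 FPKM, and CENPF, a kinetochore protein gene, fell by 1.72. Of 39 G1/S and DNA replication genes, 12 fell, 0 rose and 27 did not pass (19 down over the list alone), with a median of -0.68 (9.94e-07; adjusted p = 0.501 with an estimated correlation) and of -1.23 without those libraries. The replication helicase gene MCM2 went from 35.3 ± 4.77 to 14.8 ± 4.35 FPKM, and TYMS, thymidylate synthase, fell by 1.45. With all libraries CCNB1 (-1.30, limma adjusted p = 0.0815) and AURKA (-1.25, 0.0532) did not pass. The medians of both lists without control 2 and 3 rest on 1 control library, so tests on them do not measure replication. MKI67, CENPF, MCM2 and TYMS did not pass without those libraries. Of 27 quiescence and FOXO targets, 10 rose, 0 fell and 17 did not pass (14 up and 1 down over the list alone), with a median of 0.82 (7.8e-07; adjusted p = 0.327 with an estimated correlation) and of 0.95 without those libraries (adjusted p = 2.63e-09). TXNIP and the cell cycle inhibitor gene CDKN2B (log2 change 3.11; 1.65 with adjusted p = 0.00679 without control 2 and 3) led it.

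The machinery of translation moved in opposite directions. Of 57 cytosolic ribosomal protein genes, 25 rose, 0 fell and 32 did not pass (35 up over the list alone). Their median was 0.60 (camera, Benjamini-Hochberg adjusted p = 2.9e-13, and 0.466 with an estimated correlation), and 0.80 without control 2 and 3. RPL13 rose from 143 ± 68.2 to 471 ± 31.9 FPKM and RPL23 by 1.13 (0.0579 and 0.107 without those libraries). Of 33 ribosome biogenesis genes, 13 fell, 0 rose and 20 did not pass (19 down when adjusted over the list alone), with a median of -0.71 (6.42e-06; adjusted p = 0.425 with an estimated correlation) and of -0.62 without those libraries (4.96e-05). FBL (fibrillarin, -2.34) and BYSL (-1.44), nucleolar processing factors, fell most, and were -0.21 and -0.95 without them, not past the threshold.

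Inflammatory and antigen-presenting genes were higher in induced CFPAC-1 cells. Of 30 NF-kB and inflammatory cytokine genes, 12 rose, 0 fell and 18 did not pass (17 up over the list alone), with a median of 1.03 (camera, Benjamini-Hochberg adjusted p = 8.22e-07; adjusted p = 0.425 with an estimated correlation) and of 1.38 without control 2 and 3. The neutrophil chemokine gene CXCL8 rose from 4.66 ± 1.71 to 118 ± 31.6 FPKM and the iron-binding lipocalin gene LCN2 by 4.66, but without control 2 and 3 their adjusted p was 0.0679 and 0.316. Of 13 antigen presentation genes, 8 rose, 0 fell and 5 did not pass (9 up over the list alone), with a median of 0.96 (3.36e-05; adjusted p = 0.327 with an estimated correlation) and of 0.72 without those libraries. HLA-B rose by 2.88 and HLA-F by 1.60 (adjusted p = 0.0701 and 0.0702 without those libraries). Of 27 interferon response genes, 8 rose, 1 fell and 18 did not pass (8 up and 1 down over the list alone), with a median of 0.59 (4.94e-05; 0.425 with an estimated correlation) and of 0.42 without them. BST2 rose by 4.49 and OAS1 by 3.04; without control 2 and 3 BST2 had a log2 change of -0.06 and OAS1 of 0.48.

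Of the lists of RNA quality, replication-dependent histones were higher in induced CFPAC-1 cells. Of 11 genes, 6 rose, 0 fell and 5 did not pass (6 up over the list alone), with a median of 1.28 (camera, Benjamini-Hochberg adjusted p = 1.12e-06; adjusted p = 0.425 with an estimated correlation) and of 1.64 without control 2 and 3. HIST1H1C rose from 31.2 ± 2.47 to 335 ± 114 FPKM and HIST1H2BD from 11.0 ± 0.555 to 79.3 ± 22.2 FPKM.

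Metabolic and stress lists also moved in CFPAC-1. Of 25 cholesterol synthesis genes, 9 fell, 0 rose and 16 did not pass (18 down and 1 up over the list alone), with a median of -1.03 (camera, Benjamini-Hochberg adjusted p = 8.43e-06; adjusted p = 0.501 with an estimated correlation), but of -0.31 without control 2 and 3, where the list did not pass (0.289). Of 20 fatty acid synthesis genes, 7 fell, 1 rose and 12 did not pass (10 down and 1 up over the list alone), with a median of -0.52 (0.00451; 0.501 with an estimated correlation) and of -0.40 without them. FASN, fatty acid synthase, fell from 206 ± 93.1 to 29.4 ± 4.15 FPKM (adjusted p = 0.0612 without control 2 and 3). Of 37 oxidative phosphorylation genes, 8 fell, 0 rose and 29 did not pass (12 down over the list alone), with a median of -0.42 (0.00162; 0.501 with an estimated correlation) and of -0.31 without them, led by ATP5G1 (-1.45) and CYCS (-1.24); it did not pass without CFPAC-1 induced 1 (0.0629), nor did these genes without control 2 and 3 (0.0977 and 0.586). The 13 mitochondrially encoded mRNAs, a list of RNA quality, had a median of -0.73 (0.0154; 0.671 with an estimated correlation; 2 down, also over the list alone), with MT-ND5 at -0.88 and MT-ND6 at -0.73; it was -1.46 without control 2 and 3, and the list did not pass without control 1 or induced 1 (adjusted p = 0.417 and 0.536) or with the replicate block (0.0547). Of 21 NRF2 targets, 10 rose, 1 fell and 10 did not pass (11 up and 2 down over the list alone), with a median of 1.16 (0.000302; 0.425 with an estimated correlation) and of 0.21 without control 2 and 3 (0.00103). FTH1, the heavy chain of ferritin, rose from 896 ± 499 to 4983 ± 957 FPKM.

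Of the lists of tumour cell identity, the classical one turned its sign without the libraries that stand apart. Classical pancreatic cancer genes (15; 1 up, 0 down, 14 not passed, 1 up over the list alone) had a median of 0.97 with all libraries (camera, Benjamini-Hochberg adjusted p = 0.00387; adjusted p = 0.501 with an estimated correlation) and of -0.27 without control 2 and 3 (0.663). Basal-like genes (28; 6 up, 0 down, 22 not passed, 6 up over the list alone) had one of 0.32 (0.000982; 0.482 with an estimated correlation) and of 0.07 (0.0346). Mesenchymal transition genes (17; 4 up, 1 down, 12 not passed, 8 up and 1 down over the list alone) had one of 0.64 (0.0353; 0.357 with an estimated correlation) and of 0.45 (0.0655), and did not pass without control 1, induced 2 or induced 3 (0.0542, 0.0627 and 0.0571) or after median-of-ratios scaling, quantile normalization or the replicate block (0.0709, 0.0842 and 0.0781). VIM, an intermediate filament gene of mesenchymal cells, stood at 622 ± 69.0 and 969 ± 7.13 FPKM in control and induced CFPAC-1, and CDH1, E-cadherin, at 0.287 ± 0.175 and 0.686 ± 0.240 FPKM. In BxPC-3 VIM stood at 7.20 ± 2.84 and 10.1 ± 1.32 FPKM and CDH1 at 47.0 ± 6.22 and 46.3 ± 12.8 FPKM. KRT7, a keratin of duct epithelium, stood at 1.42 ± 0.937 and 1.43 ± 0.524 FPKM in CFPAC-1 and at 535 ± 63.9 and 494 ± 85.7 FPKM in BxPC-3. Low CDH1 and KRT7 and high VIM are not what is usually described for CFPAC-1; the identity of the libraries was not tested, so all CFPAC-1 values hold for the libraries as labelled.

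Of the cilium lists, centriole and basal body passed in CFPAC-1 (22 genes; 1 up, 4 down, 17 not passed, the same counts when adjusted over the list alone), with a median of -0.42 (camera, Benjamini-Hochberg adjusted p = 0.0112; adjusted p = 0.501 with an estimated correlation). Its members C2CD3 (-1.10) and STIL (-1.01) fell and MARK4 (0.69) rose. Without control 2 and 3 the median was -0.31 and the list did not pass (0.0751). Of 28 intraflagellar transport genes, 1 rose (KIFAP3, 0.61), 2 fell (KIF3B, -1.07, and TRAF3IP1, -0.79) and 25 did not pass, with a median of -0.17 (0.789). Medians were -0.07 for the BBSome (0.927), -0.24 for the transition zone (0.43; TMEM237 and TCTN3 fell), and -0.36 for ciliary membrane and trafficking (0.149; RAB23 fell). They were -0.47 for cilium disassembly (0.165; 3 of 13 fell), -0.30 for the motile cilia programme (0.697; 1 of 5 rose and 1 fell) and 0.19 for the Hedgehog pathway (0.206; FOXL1 rose). Without control 2 and 3, medians were 0.09 for intraflagellar transport (0.118), 0.16 for the BBSome (0.498), -0.08 for the transition zone (0.958) and -0.09 for ciliary membrane and trafficking (0.791). They were -0.47 for cilium disassembly (0.0682), 0.25 for the motile cilia programme (0.289) and -0.27 for the Hedgehog pathway (0.393), so the signs of the intraflagellar transport, BBSome, motile cilia and Hedgehog lists turned. None of the 10 single genes named here passed without those libraries. GLI1 had a log2 change of 0.37 with all libraries and of -0.37 without control 2 and 3, and HDAC6 of -0.41 and 0.19, none past the threshold.

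**Figure D2:**
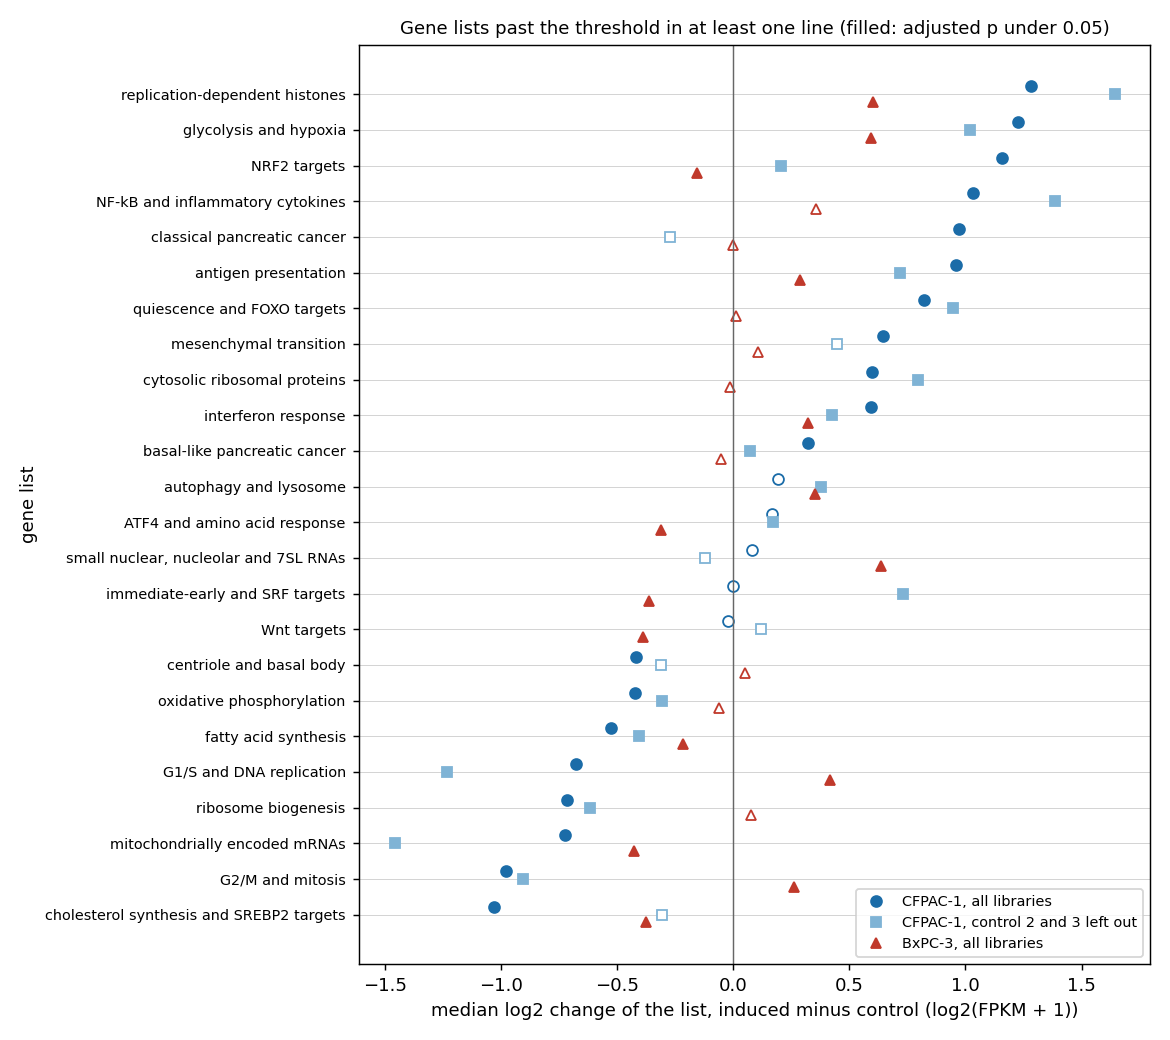
Median log2 change, induced minus control, of each gene list that passed in at least 1 line, for CFPAC-1 with all libraries (circles), CFPAC-1 without control 2 and 3 (squares) and BxPC-3 (triangles); filled symbols have an adjusted camera p under 0.05 at the preset correlation. The glycolysis and hypoxia list lay at 1.23, 1.02 and 0.59, and the G2/M list at -0.98, -0.91 and 0.26.

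Whether the lines responded alike was asked from the overlap of calls. The 7 genes that passed in both lines all rose, and 0 fell. They were PGK1, ENO2, ERO1A, P4HA2, QSOX1, PAM and CFB. ERO1A and QSOX1 are oxidases that form disulfide bonds, P4HA2 is a subunit of the collagen prolyl hydroxylase, and PAM amidates peptides. Log2 changes in CFPAC-1 and BxPC-3 were 2.51 and 1.31 for ERO1A, 1.34 and 1.28 for P4HA2, and 1.27 and 1.09 for PGK1. They were 1.08 and 1.30 for QSOX1, 0.90 and 1.05 for PAM, 2.52 and 1.91 for ENO2 and 3.67 and 2.33 for CFB. Independent lists of these sizes would share 2.98 genes that rose (one-sided Fisher's exact p = 0.0266) and 0.439 that fell. With CFPAC-1 control 2 and 3 left out, 1 control library remained in that line, and the genes that passed in both lines were not the same set. ENO2, QSOX1 and PAM then no longer passed in CFPAC-1, while CA9 passed in both lines. The overlap of that fit is therefore no support for the 7 genes as a set. With the replicate number as a block the overlap was 0. It was also 0 without BxPC-3 control 2 or induced 2, and 1 without BxPC-3 control 3 or induced 3. It was 37, 25 and 11 without BxPC-3 control 1, CFPAC-1 control 1 or BxPC-3 induced 1, and 3 or 4 without CFPAC-1 control 2, control 3, induced 2 or induced 3. Across all tested genes the changes in the lines correlated at r = 0.113 (Spearman's rho 0.0616), and at 0.0674 (rho 0.0409) without CFPAC-1 control 2 and 3. In BxPC-3 itself the changes within library number 1 and within numbers 2 and 3 correlated at -0.0091. A low correlation between the lines therefore cannot tell whether they respond differently.

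**Figure D3:**
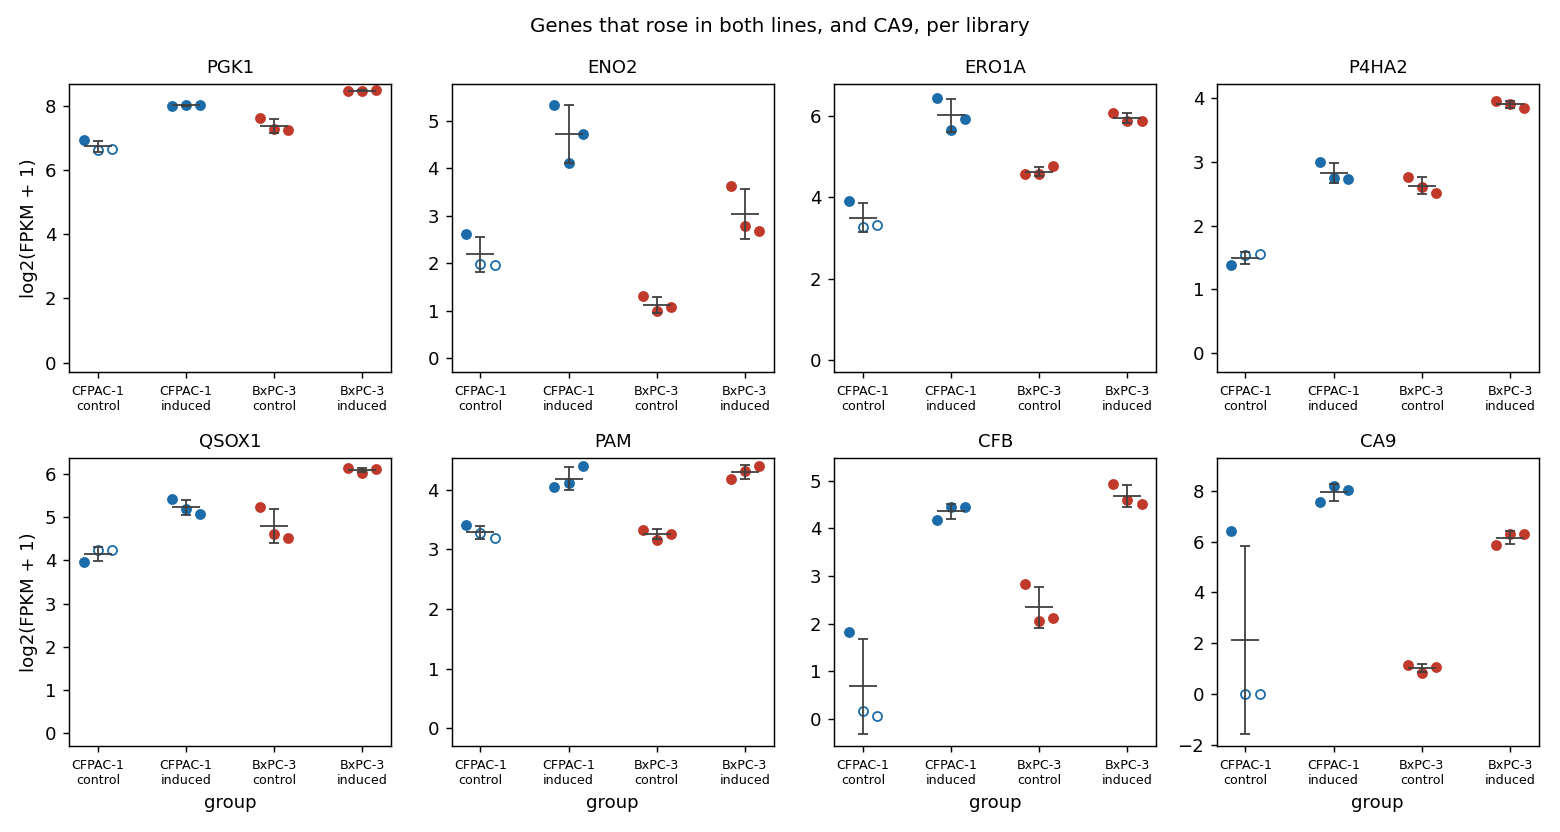
log2(FPKM + 1) per library of the 7 genes that passed in both lines and of CA9. With all libraries CA9 passed in CFPAC-1 only, although every induced BxPC-3 library also lay above every BxPC-3 control library. Points are libraries, open circles the libraries labelled CFPAC-1 control 2 and 3, and bars the mean ± SD of 3 libraries. For P4HA2 every induced library lay above every control library of its line, at mean FPKM of 1.82 and 6.12 in CFPAC-1 and of 5.19 and 14 in BxPC-3.

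The difference between the lines was tested itself, as the change in BxPC-3 minus that in CFPAC-1. It passed for 315 genes (172 higher in BxPC-3, 143 lower; limma, Benjamini-Hochberg adjusted p under 0.05), and for 3121 at an unadjusted p under 0.05. The difference was positive for S100A7 and S100A8, listed at 0 in every CFPAC-1 library, for DUOXA2 (2.93), for RAB31 (3.01) and for the monocyte co-receptor gene CD14 (2.79). For RAB31 it came mostly from a fall by 2.34 in CFPAC-1, beside a change of 0.67 in BxPC-3 that did not pass. CD14 had changes of -1.29 in CFPAC-1 and 1.5 in BxPC-3, neither past the threshold; without control 2 and 3 that in CFPAC-1 was -0.03 and that in BxPC-3 passed (adjusted p = 0.00743). S100P (-4.32), TMEM158 (-4.20), CXCL8 (-4.04), the cytokine gene IL32 (-3.55) and the lysyl oxidase gene LOXL4 (-3.52) changed more in CFPAC-1. S100P went from 10.0 ± 12.9 to 78.7 ± 7.00 FPKM in CFPAC-1 and from 212 ± 69.4 to 117 ± 1.32 FPKM in BxPC-3. Of these 10 genes only CD14 and S100P passed without CFPAC-1 control 2 and 3, with smaller differences of 1.52 and -2.42 (adjusted p = 0.0466 for each). Those of RAB31, TMEM158, CXCL8, IL32 and LOXL4 were then 3.11, -3.04, -3.57, -2.18 and -2.84. In that fit 55 genes passed in all (23 higher, 32 lower), 29 of them among the 315. With the replicate number as a block the difference passed for 2 genes. The count was 0, 13, 17 and 20 without BxPC-3 control 2, control 3, induced 2 or induced 3, and 722 and 478 without BxPC-3 control 1 or induced 1. It was 4148, 9 and 11 without CFPAC-1 control 1, 2 or 3, and 23 and 50 without CFPAC-1 induced 2 or 3.

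Among lists that passed, NRF2 targets and the cell cycle had the largest median differences. For NRF2 targets it was -1.32 (2 of 21 lower in BxPC-3, 13 lower and 2 higher over the list alone), and -0.69 without control 2 and 3. The camera adjusted p with all libraries was 2.01e-06 (Benjamini-Hochberg), and 0.388 with an estimated correlation. The difference was 1.25 for G2/M and mitosis (9 of 47 members higher in BxPC-3, 31 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 5.13e-13; adjusted p = 0.448 with an estimated correlation) and 1.16 for G1/S and DNA replication (3 of 39, 23 over the list alone; 2.3e-10; 0.448). It was -0.60 for cytosolic ribosomal proteins (3 of 57 lower in BxPC-3, 16 over the list alone; 1.44e-13; 0.448), -0.79 for quiescence and FOXO targets (4 of 27, 7 over the list alone; 1.48e-06; adjusted p = 0.388 with an estimated correlation) and -0.92 for NF-kB and inflammatory cytokines (4 of 30, 5 lower and 1 higher over the list alone; 0.000159; 0.448). Without control 2 and 3 the differences of these last 5 lists were 1.15, 1.68, -0.79, -0.89 and -0.97. In all, 16 lists passed, 10 of them also without those libraries. Passing only without them were immediate-early and SRF targets (-0.97, adjusted p = 1.43e-05), Wnt targets (-0.60, 0.0221), p53 targets (-0.10, 0.0118), cholesterol synthesis (-0.26, 0.0348), the unfolded protein response (-0.28, 0.00768), autophagy and lysosome (-0.17, 0.0122) and mitochondrially encoded mRNAs (0.88, 0.00768). For glycolysis and hypoxia the difference was -0.63 (0.00114; adjusted p = 0.448 with an estimated correlation; 1 of 30 lower, 7 lower and 1 higher over the list alone), and -0.17 without control 2 and 3, where it did not pass (0.284).

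With all libraries, some lists passed in 1 line only. In BxPC-3 the medians of lists that passed in CFPAC-1 alone were -0.06 for oxidative phosphorylation (camera, Benjamini-Hochberg adjusted p = 0.0548; 0.0326 without CFPAC-1 control 2 and 3), 0.36 for NF-kB and inflammatory cytokines (0.16; 8 up and 2 down when adjusted over the list alone) and 0.11 for mesenchymal transition (0.16; MMP9 rose by 1.86). They were -0.01 for cytosolic ribosomal proteins (0.239), 0.08 for ribosome biogenesis (0.636), 0.01 for quiescence and FOXO targets (0.645), 0.00 for classical pancreatic cancer (0.645) and -0.05 for basal-like pancreatic cancer (0.762; SPRR1B, a cornified envelope gene, rose by 1.31). In CFPAC-1 those of lists that passed in BxPC-3 alone were 0.19 for autophagy and lysosome (0.092; 4 up, 1 down), 0.17 for ATF4 and amino acid response (0.514; 4 up, 1 down). They were 0.00 for immediate-early and SRF targets (0.699; 3 up, 2 down), -0.02 for Wnt targets (0.348; 3 up) and 0.08 for small nuclear, nucleolar and 7SL RNAs (0.788). Without control 2 and 3, however, 3 of these lists passed in CFPAC-1: autophagy and lysosome with a median of 0.38 (7.02e-06), ATF4 and amino acid response with 0.17 (0.0128) and immediate-early and SRF targets with 0.73 (0.00819), the last 2 opposite in sign to BxPC-3. Wnt targets had a median of 0.12 there (0.272) and small nuclear RNAs one of -0.12 (0.927). Among their members the cathepsin gene CTSL rose by 2.25 and the stress factor gene DDIT3 by 2.21, and the serine synthesis gene PSAT1 fell by 1.24, all past the threshold also without control 2 and 3.

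The remaining lists did not pass in either line with all libraries. Median log2 changes in CFPAC-1 and BxPC-3 were -0.58 and -0.50 for Notch targets, -0.06 and -0.13 for YAP TEAD targets, -0.23 and 0.16 for TGF-beta targets, and -0.15 and -0.05 for p53 targets. They were 0.16 and 0.06 for the unfolded protein response, 0.44 and -0.10 for extracellular matrix, 0.25 and -0.06 for duct cell and mucin markers and 0.08 and 0.08 for epithelial junction genes. Their camera p-values with Benjamini-Hochberg adjustment ran from 0.102 to 0.947 in CFPAC-1 and from 0.166 to 0.645 in BxPC-3. Without control 2 and 3 the unfolded protein response (0.25, adjusted p = 0.00503) and p53 targets (0.07, 0.032) passed in CFPAC-1. The other 6 did not (0.142 to 0.847), with medians of -0.08 for Notch, 0.15 for YAP TEAD and 0.17 for TGF-beta targets, 0.03 for extracellular matrix, -0.03 for duct cell and mucin markers and 0.00 for epithelial junction genes. With all libraries, for TGF-beta targets, the unfolded protein response and epithelial junction genes in BxPC-3 and p53 targets in CFPAC-1 the test pointed the other way than the median. Of markers of other cell types, 4 fibroblast, 2 immune cell, 1 acinar and endocrine and 0 endothelial genes were expressed highly enough to be tested, so these lists had no test. Of these markers, LUM (fibroblast; log2 change 4.30) and CD68 (immune cell; 2.16) rose in CFPAC-1, with 0.83 and 1.61 without control 2 and 3, not past the threshold, and CEL (acinar) had a change of 0.12. In BxPC-3 the log2 changes with all libraries were 0.08 for LUM, -0.19 for CD68, 1.5 for CD14 and 0.27 for CEL, none past the threshold.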

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

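The tests of the explanations below were chosen after the results were seen, except the test of a wider hypoxia-type response.

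The libraries labelled CFPAC-1 control 2 and 3 stood apart from the other 4 of their line. A technical split like that of library 1 in the other groups is argued against, since the largest SD of that kind elsewhere was 0.547 of the SD here. An effect of control culture on the same cells is not decided. Control 1 correlated better with the induced libraries than with control 2 and 3, by 0.118. This value restates the pattern that raised the question and rests on the single library control 1, so it cannot decide it. The order alone is not particular to CFPAC-1: in BxPC-3 control 1 also correlated better with the induced libraries (r = 0.967, 0.960 and 0.962) than with control 2 and 3 (0.952 and 0.947), by 0.013 on average. Another cell population stays open as a candidate explanation: 79 genes were at 10 FPKM or more in one set and 0.2 or less in the other, while on-off genes between library 1 and libraries 2 and 3 numbered 139 in this group and 2, 1 and 1 in the others. Of the 79 genes, 40 were at 10 FPKM or more in each of the other 4 libraries and at 0.2 or less in both control 2 and 3. Those 40 argue against a mixture with more than a small share of the cells of the other 4 libraries. Whether the population is another line, another mixture or a clone was not tested. In addition, 82 genes on in every BxPC-3 library were off in both, which argues against an exchange with BxPC-3.

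Library number 1 stood apart from numbers 2 and 3 in each group. Lower depth is argued against, since number 1 had the lowest relative depth in only 1 of 4 groups. A batch effect shared by the groups cannot be told apart from separate effects: the differences correlated across genes at -0.068, 0.287 and 0.151 between groups (median 0.151), neither all high nor all near 0. Culture or passage differences may lie behind it too, and no biological explanation was tested because the labels give none.

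The glycolysis and hypoxia list was higher in induced cells of both lines. The control libraries that stand apart are argued against as the cause, since the list's median in CFPAC-1 was 1.02 without them, and so is library number 1 alone or numbers 2 and 3 alone in BxPC-3, since the smaller of its 2 medians within numbers was 0.69. In CFPAC-1 no such test was made for numbers 2 and 3, whose controls stand apart. A wider hypoxia-type response is consistent with HIF-responsive genes outside the list, whose smaller median in the lines was 0.47. This remains a hypothesis: serum starvation, cilium growth, cell density and nutrient use came together in the induced cultures, and the list's adjusted p was 0.327 with an estimated correlation.

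The response differed between the lines, by the test of the difference itself, for 10 named genes. The changes in BxPC-3 minus CFPAC-1 were 5.34 for S100A7, 4.37 for S100A8, 3.01 for RAB31, 2.93 for DUOXA2, 2.79 for CD14, -4.32 for S100P, -4.20 for TMEM158, -4.04 for CXCL8, -3.55 for IL32 and -3.52 for LOXL4 on the log2 scale. It also differed for 16 gene lists, with median differences of 0.45 for centriole and basal body, 1.16 for G1/S and DNA replication, 1.25 for G2/M and mitosis, -0.79 for quiescence and FOXO targets, -0.63 for glycolysis and hypoxia, -0.60 for cytosolic ribosomal proteins, 0.81 for ribosome biogenesis and -0.30 for ATF4 and amino acid response. The others were -1.32 for NRF2 targets, -0.24 for interferon response, -0.67 for antigen presentation, -0.92 for NF-kB and inflammatory cytokines, -0.96 for classical pancreatic cancer, -0.50 for basal-like pancreatic cancer, -0.57 for duct cell and mucin markers and -0.53 for histones, a list of RNA quality. The difference of S100A7 lost its call without a filter (limma, Benjamini-Hochberg adjusted p = 0.0671) and with the replicate block (0.0764). It was also lost on leaving out single libraries, from CFPAC-1 induced 3 (0.0658) to BxPC-3 control 2 (0.0861). Every gene and list difference given so far includes the libraries labelled CFPAC-1 control 2 and 3. Without them CD14 (1.52) and S100P (-2.42) passed and the other 8 genes did not, with 3.11 for RAB31, -3.04 for TMEM158, -3.57 for CXCL8, -2.18 for IL32, -2.84 for LOXL4 and the same values for S100A7, S100A8 and DUOXA2. Of the 16 lists 10 passed. With an estimated correlation 0 of the 16 lists passed (adjusted p = 0.388 to 0.552). The duct cell list did not pass under 12 further planned settings, among them median-of-ratios scaling (0.123) and the replicate block (0.098). The centriole list did not pass without CFPAC-1 control 1, induced 2 or induced 3 or BxPC-3 induced 1 (0.0621, 0.079, 0.0638 and 0.0959), nor the ATF4 list without CFPAC-1 control 1 or BxPC-3 induced 1 (0.319 and 0.0959). The interferon list had a median of -0.0027 without BxPC-3 control 1 (0.256). Without a filter the ATF4 and interferon lists did not pass (0.227 and 0.0741), and at a mean FPKM of at least 5 the ATF4 and antigen presentation lists did not (0.0956 and 0.0522).

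Other splits of the libraries were counted for each result. The 6 libraries of a line can be split in only 10 ways, too few for a share under 0.05. In CFPAC-1 the real split gave 2138 genes and the highest other 1109, with 1143 and 731 at least 2-fold; in BxPC-3 it gave 43 and 4, with 38 and 4. For lists the real split gave 19 and the highest other 17 in CFPAC-1, and 15 and 16 in BxPC-3, where 3 of the 10 splits gave 15 or more. The number of lists in BxPC-3 is thus reached by other splits, so chance is not excluded for it. For the difference between lines, 4 of 100 splits gave 315 genes or more, a share under 0.05, but all 4 kept the real groups of CFPAC-1. Of the 12 splits that did so, 4 gave as many, up to 382 with the groups of BxPC-3 mixed and 574 with them exchanged, which turns the contrast into the sum of the changes in the lines, while splits that mixed the CFPAC-1 groups gave at most 85. The count thus rests on the grouping of CFPAC-1, whose 10 splits are too few for a share under 0.05, and it is reached without the real groups of BxPC-3, so chance is not excluded for the difference between lines. For the overlap of the lines, 1 of 100 splits gave 7 genes, the real one, and the highest other gave 2. Other splits of BxPC-3 call at most 4 genes and cannot reach 7, which leaves the 10 splits of CFPAC-1, too few for a share under 0.05, so chance is not excluded. For lists that differ between lines, 19 of 100 splits gave 16 or more, up to 21, so chance cannot be excluded for that count.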

How the results depend on the processing

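Fits without the libraries labelled CFPAC-1 control 2 and 3, with a term for library number 1 or with libraries numbered 2 and 3 only were added after seeing the data, and the others were planned; each line alone cannot give the difference between the lines. Every value below is a count of results past the threshold or a log2 change. The depth in reads is not known, so how far low genes are limited by it cannot be said. Where no construction is named, the cause was not tested.

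Of 128 calls of named genes, 34 were kept without CFPAC-1 control 2 and 3, 92 kept their direction only and 2 reversed: BST2 in CFPAC-1 to -0.062 and COL5A1, which fell by 2.00 with all libraries, to 0.017, also with the BxPC-3 term added. Each line alone kept 26 of 118 calls, the replicate block 77 of 128, and leaving out CFPAC-1 control 2 or control 3 kept 48 or 50. Calls kept numbered 103 with a pseudocount of 0.1, 61 without a filter, 104 under TPM, 114 and 116 under median-of-ratios and quantile scaling, and 128 with a variance trend, with no reversal. Genes named by size in a line had no overlap of induced and control values, so leaving out libraries could not turn their direction. For these genes a kept direction is no sign of stability. Of 50 list results, 40 were kept without those 2 libraries, 7 weakened and 3 reversed: the classical list to -0.27 in CFPAC-1 and to 0.24 in the difference between lines, and the duct cell list to 0.10 in that difference, also with the BxPC-3 term added. The mesenchymal list in CFPAC-1 went to -0.045 without a filter, which admits many genes near 0, and the mitochondrial list to 0.10 with libraries 2 and 3 only. With correlations estimated per list, 0 of the 19, 15 and 16 lists passed, because the estimated correlations widen the test; their adjusted p ran from 0.327 to 0.717 in the lines.

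Counts past 1.5 times of the value given were as follows. For CFPAC-1, 2138 became 1329 at a mean FPKM of at least 5 (fewer genes tested), 364 with each line alone (fewer samples), 222 without control 2 and 3, 4004 with the number 1 term, 8714 with libraries 2 and 3 only and 717 without control 2 and 3 with the BxPC-3 term. At least 2-fold, 1143 became 587 without a filter, 732 at the stricter filter, 265 alone, 212, 3285 and 482 in the left-out, 2-and-3 and combined fits. For BxPC-3, 43 became 25 with a pseudocount of 0.1, 73 without a filter, 11 at the stricter filter, 13 alone, 88 with the number 1 term, 5396 with libraries 2 and 3 only and 104 in the combined fit. At least 2-fold, 38 became 25, 23, 11, 13, 693 and 74 with the pseudocount, no filter, the stricter filter, alone, 2 and 3 only and combined. For the difference, 315 became 163 with the pseudocount, 162 at the stricter filter, 191 under TPM, 55 without control 2 and 3, 1862 with the number 1 term and 8023 with 2 and 3 only. For genes in both lines, 7 became 4 at the stricter filter, 2 alone, 26 with the term, 2162 with 2 and 3 only and 12 combined. BxPC-3 alone with the number 1 term called 39 genes (35 up, 4 down).

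Leaving out each library in turn gave 506 to 5403 genes in CFPAC-1 (413 to 3000 at least 2-fold), 2 to 249 in BxPC-3 (2 to 197), 0 to 4148 for the difference, 0 to 37 in both lines, and 18 to 21, 11 to 18 and 15 to 19 lists. Where a group was left with 2 libraries, it shared the spread of the others.

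With the replicate number as a block, 1615 genes passed in CFPAC-1, 0 in BxPC-3, 2 in the difference between lines and 0 in both lines, with 0 at least 2-fold in BxPC-3, and 17, 16 and 18 lists passed. Beside the 0 in BxPC-3 stand 43 genes by limma without the block and 1096 at an unadjusted p under 0.05. The numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated at -0.06, -0.02 and -0.08 in CFPAC-1 and at 0.15, 0.11 and 0.05 in BxPC-3, and not every library correlated best with its own number.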

Other observations

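The test of the chromosome 19 segment and that of the HIF-responsive genes were written before their values were seen; the choice to look at this segment followed from its genes among the largest falls in CFPAC-1.

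HIF-responsive genes outside the glycolysis and hypoxia list were higher in induced cells of both lines. Of 22 tested genes, such as HILPDA, PFKFB4 and EGLN1, 17 had a positive change in each line, 5 rose in CFPAC-1 and 0 passed singly in BxPC-3. The median log2 change was 0.69 in CFPAC-1 (camera of limma, p = 9.17e-05; p = 0.078 with an estimated correlation) and 0.47 in BxPC-3 (p = 0.000141; 0.0849). Without CFPAC-1 control 2 and 3 the median in CFPAC-1 was 0.63, with 20 of 22 positive. A response to low oxygen or to the same transcription factors may thus reach beyond the fixed list, as a hypothesis, with the smaller median of 0.47 as its test.

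A block of neighbouring genes on chromosome 19 was high in the libraries labelled CFPAC-1 control 2 and 3. PSMC4, a proteasome ATPase gene (chromosome 19, 39971005 to 39981441, GRCh38), TIMM50 and FBL are among them. The kinase gene AKT2 had a mean of 80.1 FPKM there and of 4.32 FPKM in the other 4 libraries of the line, and the elongation factor gene SUPT5H 181 and 16.9 FPKM; these were chosen after their values were seen. The highest median of any 10 consecutive tested genes in these libraries was 3.35, at 39436156 to 39981441 on this chromosome, against 1.58, 1.05 and 1.43 for the highest such runs of libraries 2 and 3 against 1 in the other groups. These runs are not on a like scale, since 3.35 is a difference from the other 4 libraries of the line. The SD of the log2 difference between library 1 and the mean of 2 and 3 was also larger in CFPAC-1 control, at 1.08 against 0.593, 0.534 and 0.539. A copy-number gain of the segment in the cells behind these libraries may be a hypothesis. Of 17 other tested genes within 0.5 Mb of PSMC4, 10 (58.8%) were higher by over 1 log2, against 11.1% of all tested genes; the bounds set beforehand were 80% for a gain and 30% against it, so the test left it open.

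Genes of the cilium and of Hedgehog signalling that lay under the filter are given as values per library, in the order 1, 2, 3. IFT88 stood at 0.676, 1.44 and 1.62 FPKM in CFPAC-1 control and 0.970, 0.653 and 0.718 in induced, and at 0.279, 0.486 and 0.462 in BxPC-3 control and 0.604, 0.579 and 0.880 in induced. PTCH1, a target of the Hedgehog pathway, stood at 0.652, 0.174 and 0.150, then 0.926, 0.409 and 0.527 FPKM in CFPAC-1, and at 0.665, 0.216 and 0.192, then 1.01, 0.241 and 0.287 in BxPC-3. SMO was listed at 0 in every BxPC-3 library and at most at 0.279 FPKM in CFPAC-1. FOXJ1, the regulator of motile cilia, stood at 2.31 and 1.74 FPKM in the libraries labelled CFPAC-1 control 2 and 3 and at most at 0.727 FPKM elsewhere. CDKN1B had log2 changes of 0.84 and 1.16, FOS of 1.65 and 0.75, and MYC of -0.97 and -1.54 in CFPAC-1 and BxPC-3, none past the threshold, with MYC at 0.24 in CFPAC-1 without control 2 and 3. In BxPC-3 the changes within library number 1 and within numbers 2 and 3 were opposite for FOS (3.08 and -0.42) and MYC (2.24 and -3.44), and FOS had a change of -0.22 without control 1; for CDKN1B they were 0.39 and 1.54. ACTB fell by 1.39 in CFPAC-1 (limma, Benjamini-Hochberg adjusted p = 0.0289; 0.488 without control 2 and 3) with a change of -0.42 in BxPC-3.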
